A study of Mus musculus with 16 samples.

How the data were processed

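The data were RNA-seq expression values of 16 mouse aortas without adventitia, 8 from mice infused with saline and 8 from mice infused with Ang II for 7 days. Total RNA was extracted with Trizol and made into mRNA-seq libraries, per the labels' protocols. The authors deposited one table of FPKM (fragments scaled by transcript length and by the reads of the library) for 54532 genes, named by Ensembl gene IDs and symbols. The genome build was GRCm38 (mm10), per the submitters' processing notes; the aligner, the counting tool, their versions and whether strand was used in counting are not given in the sources used here. Group and replicate number were taken from the sample titles, and each column was matched to its sample by the library name in the labels. The table also holds a length per gene in bases, as deposited by the authors, which is not the length behind the FPKM.

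Gene IDs were matched to the GENCODE M21 annotation, where 99.77% were found and 98.3% of those had the same coordinates. FPKM values were multiples of what 1 read is worth once the mean transcript length of a gene, rounded down, was used. In each library 95.8% to 96.3% of values above 0 came out whole within 0.02 of a read. Reads were recovered for 31391 of 31423 genes above 0, for 968 of them with another length; Lox was among those not recovered. The FPKM totals ran from 14606864 reads (Saline 2) to 19988730 (Ang II 7), and the recovered reads summed to 99.94% to 100.26% of them. At these depths 1 read in a transcript of 1 kilobase is worth 0.0500 to 0.0685 FPKM. The 56 pairs of libraries within groups were checked for libraries sequenced again or copied, and none was found (lowest chi-square per degree of freedom 18.6). This does not show that libraries came from separate mice. Overlap of exons between gene models was measured with bedtools 2.31.1.

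The main test was limma 3.58.1 in R 4.3.3 with an intensity trend on log2(FPKM + 1), for genes with a mean FPKM of at least 0.5 over the 16 libraries. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and no covariate. Errors printed with FPKM are standard deviations over 8 libraries. Slc1a5 also had an exact permutation test. Gene lists were tested with limma camera, which compares a list with all other genes, at a preset correlation of 0.01 between genes, with adjustment over the 37 lists that had at least 5 tested members. Camera was run again with a correlation estimated from the data. Of 40 lists, 3 were too small to test, and of the 14 lists called at the preset correlation, 4 held with the estimated correlation: cell cycle (adjusted p = 0.0369), collagens and matricellular proteins (0.0255), cross-linking (0.0215) and matrix-degrading proteases (0.0491). Principal components, exact permutation tests and correlations were computed in R and in Python 3.11.15 with scipy 1.17.1 and numpy 2.4.6.

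The groups, the tests, the 40 gene lists and the rule for named genes were fixed before the data were examined. The rule took genes past the threshold. It took the 10 largest increases and the 10 largest decreases among genes with at least 2 FPKM in the higher group, leaving out predicted genes, pseudogenes and immune receptor segments. From each list it took up to 2 members that rose and 2 that fell with the smallest adjusted p and a mean of at least 1 FPKM. It always took Slc1a5, Acta2, Myh11, Tagln, Eln, Lox, Mmp2, Mmp9, Spp1, Agtr1a and Apoe, and the text names a selection. Some genes that the rule took are not reported here. The glycolysis list has 18 symbols and 19 tested entries, because Aldoa has 2 gene IDs, and 5 symbols of the lists were absent from the table.

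The tests were checked on simulated data with a set of changed genes, drawn from the means, spreads and library sizes of these 16 libraries. Of the genes changed 1.5-fold limma recovered 26.9%, of those changed 2-fold 73.1% and of those changed 4-fold 87.9%, with 5 false calls among 14919 genes tested. Only 67, 67 and 66 genes were changed at these sizes, far fewer than passed in the data. That makes the adjusted threshold stricter, so these shares are not the power of the real comparison. Camera called the simulated list of changed genes and 0 of 39 random lists. The simulated genes were drawn independently of each other, so this does not check camera on lists of correlated genes. In 99 other splits of the 16 real libraries into 8 and 8, camera called a median of 12 lists. Many of these splits were uneven in Ang II libraries, so they are not free of the treatment difference. The alternatives fixed before the data were a pseudocount of 0.1, no filter, a filter at a mean of 1 FPKM, quantile normalization, scaling by median ratios, the replicate number as a block, sample weights, an adipocyte score as a covariate, leaving out each library, a Wilcoxon rank-sum test (exact where there are no ties) and, for lists, the estimated correlation. Chosen after seeing the data were limma voom on the recovered reads, removal of GC and length trends (natural splines per library), a macrophage and monocyte score as a covariate, leaving out Saline 7 and 8, Saline 2, 7 and 8, or Ang II 1 and 3, taking the reads of the 100 genes with the most reads out of each library total and, for the spread within groups, centring each gene on its group mean. A list of targets of the transcription factor ATF4 and the transcription factor families of the annotation were also tested after seeing the data.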

Results

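RNA was sequenced from the aortas of male mice that the labels give as lacking apolipoprotein E (Apoe-/-, strain C57BL/6j) after 7 days of infusion by osmotic pump. Apoe-/- mice carry high plasma cholesterol, and angiotensin II (Ang II), a hormone that constricts arteries, is infused in them to model aortic wall disease. The outer layer of the wall, the adventitia, had been taken off, so the samples held mainly the media, whose main cell is the vascular smooth muscle cell. There were 8 libraries from mice given saline and 8 from mice given Ang II at 1000 ng per kg per min. The labels name each sample separately and do not state the mouse behind it, so p-values measure the spread between these 16 samples. The FPKM totals of the libraries were 14606864 to 17590088 reads with saline and 15779125 to 19988730 reads with Ang II. The comparison addresses what Ang II does to gene expression in the wall, with the glutamine transporter gene Slc1a5 named in the title of the study.

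With Ang II, genes of the extracellular matrix and of cell division were higher, and Slc1a5 and part of the contractile genes of smooth muscle were lower. Eln, which encodes elastin, rose from 1600 ± 905 to 10799 ± 3463 FPKM (mean ± SD, n = 8 per group), a 7.15-fold change on the log2(FPKM + 1) scale. Lox, whose enzyme cross-links elastin and collagen, rose from 25.04 ± 10.8 to 160 ± 32.9 FPKM. Slc1a5 fell from 169 ± 51.6 to 71.3 ± 15.1 FPKM. Myh11, the smooth muscle myosin heavy chain, fell from 1561 ± 275 to 852 ± 169 FPKM.

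Of 15007 genes tested with limma, 5172 changed at an adjusted p under 0.05 (Benjamini-Hochberg). Of these, 1431 were higher and 3741 lower with Ang II, and 380 were at least 2-fold higher and 486 at least 2-fold lower. The 2-fold counts were 659 and 888 with a pseudocount of 0.1. With voom 830 were at least 2-fold higher, and after median ratio scaling 313 at least 2-fold lower. With the adipocyte score as a covariate 745 genes were higher and 1697 lower, and with the macrophage and monocyte score 777 and 1997. The split into higher and lower depended on how libraries were scaled to each other. The median log2 fold change over all tested genes was -0.12 with the FPKM as deposited, and the fold changes below are relative to saline on that scale. After scaling by the median ratio between libraries, that median was -0.002 and the counts were 2241 higher and 2115 lower, and after quantile normalization they were 2270 higher and 2374 lower. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. Without the libraries Saline 7 and Saline 8, which stood apart on the first principal component (46.9% of the variance), 1270 genes were higher and 3969 lower. Without Saline 2 as well, the counts were 1208 and 3929. The 100 genes with the most reads, 1 set taken on the mean share over the 16 libraries, held a larger share of the reads in each Ang II library than in any saline library. Among them the mean share of Eln rose from 0.439% to 2.96% of the reads and that of mt-Co1 from 2.55% to 3.70%, while that of Flna fell from 1.27% to 0.778%.

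**Figure D1:**
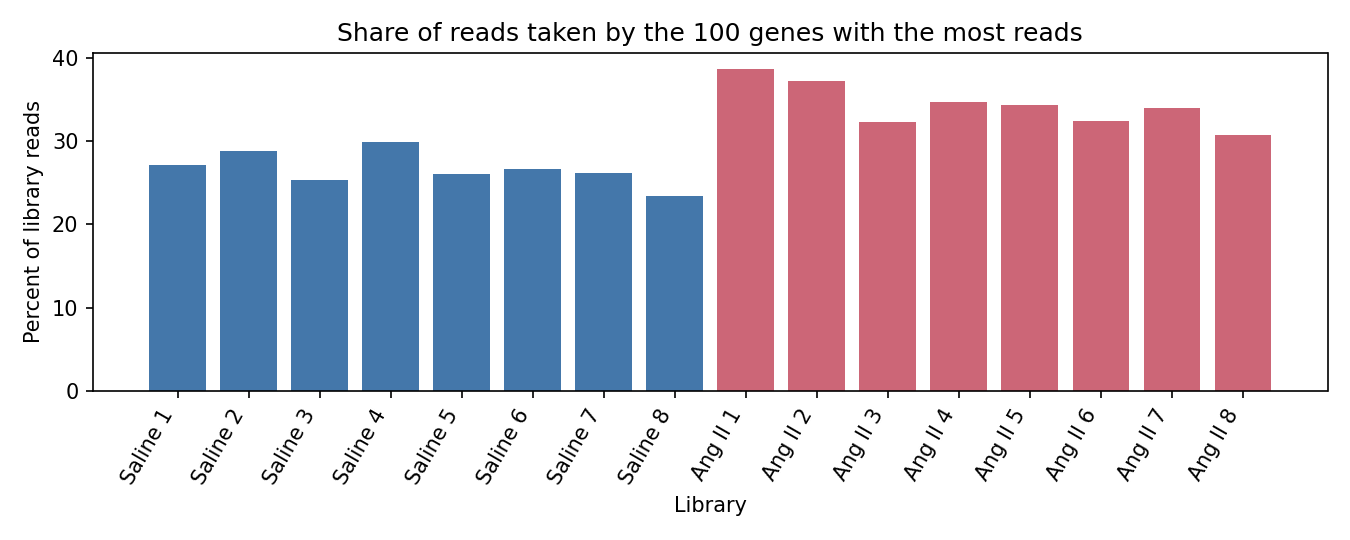
Each bar is the percent of the reads of 1 library (vertical axis) held by the 100 genes with the most reads, with the 16 libraries along the horizontal axis, saline in blue and Ang II in red. The 100 genes are the same set for every library, taken on the mean share of reads over the 16 libraries. The share was 23.4% to 29.9% in the 8 saline libraries and 30.7% to 38.7% in the 8 Ang II libraries.

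The largest increases included secreted and matrix-binding proteins. Smoc2, a matricellular protein, rose from 5.36 ± 2.18 to 106 ± 48.0 FPKM (log2 fold change 4.05, SE 0.27, limma adjusted p = 3.77e-08). Igfbp2, a binding protein of insulin-like growth factors, rose by 3.97 on the log2 scale, and the metalloprotease gene Adam12 by 3.68. Esm1 rose by 3.44, Thbs1 (thrombospondin 1) by 3.34 and the mitotic kinase gene Pbk by 2.86. With the adipocyte score as a covariate the rise of Thbs1 was 2.16 (SE 0.59). Every Ang II library lay above every saline library for Smoc2, Igfbp2, Adam12, Esm1, Pbk and Eln, and 7 of 8 did so for Thbs1. Spp1 (osteopontin) had a log2 fold change of 3.11 with an SE of 1.03 (limma adjusted p = 0.0266). Only 1 Ang II library lay above every saline library for Spp1, and 18.8% of its exon bases overlap the gene model Gm42793, so its level is uncertain. Its call was lost without Saline 7 (limma adjusted p = 0.0543) and without Ang II 6 (limma adjusted p = 0.0532).

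Among the largest decreases, Adamts15, a metalloprotease of proteoglycans, fell from 30.9 ± 8.85 to 2.59 ± 0.498 FPKM (log2 fold change -3.11, SE 0.16, limma adjusted p = 2.46e-09). Igfbp5 had a log2 fold change of -3.08, AI838599 of -2.99, Tppp3 of -2.84, Tcap of -2.47 and Selenbp1 of -2.44. The glutathione transferase gene Gstm1 had a log2 fold change of -2.37, Cyp4b1 of -2.19, Klk10 of -2.17 and Adm (adrenomedullin, a vasodilator peptide) of -2.16. For each of these 10 genes all 8 Ang II libraries lay below every saline library.

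Slc1a5 (ENSMUSG00000001918, chromosome 7, 16781340 to 16798274, plus strand, GRCm38) encodes a neutral amino acid transporter that carries glutamine into cells. Its log2 fold change was -1.21 with an SE of 0.16 (limma adjusted p = 2.92e-05). The 8 saline libraries held 122 to 282 FPKM and the 8 Ang II libraries 58.8 to 106 FPKM. An exact two-sided permutation test gave p = 0.000155, the smallest that 12870 assignments of 8 against 8 can give. After scaling by the median ratio the log2 fold change was -1.06. Of 14 white adipocyte markers 4 fell with Ang II, and with the adipocyte score as a covariate Slc1a5 had a log2 fold change of -0.90.

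Other genes of glutamine transport and use went both ways. Of 29 tested members, 9 rose and 6 fell over all genes tested, and 10 rose and 6 fell adjusted over the list alone. Psat1, an enzyme of serine synthesis that uses glutamate, rose from 2.73 ± 1.07 to 17.1 ± 6.02 FPKM. Asns (asparagine synthetase, which uses glutamine) rose from 1.03 ± 0.322 to 5.86 ± 1.84 FPKM. Glul, the glutamine synthetase, fell from 288 ± 81.7 to 85.2 ± 23.7 FPKM (log2 fold change -1.73). After median ratio scaling 13 members rose and 4 fell. The list was called higher by camera (median 0.18, adjusted p = 0.0258, and adjusted p = 0.261 with an estimated correlation). Without Ang II 1 it was not called (median 0.10, adjusted p = 0.0572).

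**Figure D2:**
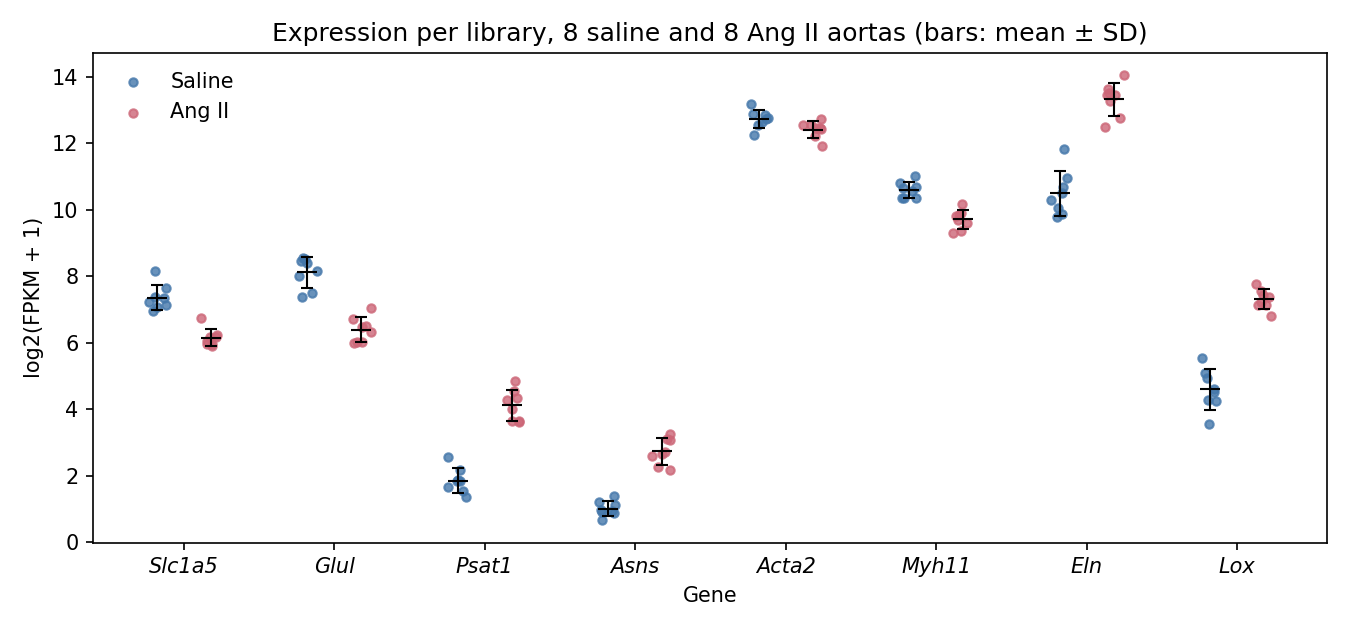
Each point is 1 library, with log2(FPKM + 1) on the vertical axis and 8 genes along the horizontal axis, saline in blue and Ang II in red; black bars are the mean ± SD of 8 libraries. All Ang II points lie below the saline points for Slc1a5, Glul and Myh11 and above them for Psat1, Asns, Eln and Lox, while the Acta2 points overlap.

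Collagen and matricellular genes rose as a group: 18 of 23 were higher and 1 lower, or 19 and 1 adjusted over the list alone (median log2 fold change 1.35, camera adjusted p = 3.7e-18, and 0.0255 with an estimated correlation). Col1a1 rose from 432 ± 85.5 to 1895 ± 593 FPKM, Tnc (tenascin C) from 29.3 ± 6.61 to 112 ± 16.4 FPKM and Fn1 (fibronectin) from 774 ± 346 to 2995 ± 1244 FPKM. Col14a1 fell from 11.6 ± 3.84 to 5.36 ± 1.496 FPKM. In the cross-linking list 13 of 17 genes rose and none fell, and 15 rose adjusted over the list alone (median 0.51, camera adjusted p = 3.09e-10, and 0.0215 with an estimated correlation). Loxl2 rose from 7.07 ± 2.42 to 40.1 ± 6.49 FPKM. Of 22 matrix-degrading proteases 8 rose and none fell by either adjustment (median 0.56, camera adjusted p = 3.03e-06, and 0.0491 with an estimated correlation). Their median ran from 0.07, with the macrophage and monocyte score as a covariate, to 1.05, with voom, over the alternatives. Plau, the urokinase, rose by 2.32 on the log2 scale and Mmp2 (gelatinase A) by 1.79. Mmp9 (gelatinase B) held 0.60 ± 0.434 FPKM with saline and 4.82 ± 11.03 FPKM with Ang II, a difference that did not pass the test (limma adjusted p = 0.283); Ang II 1 alone held 32.0 FPKM.

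Of the 14 elastic fibre genes tested, 6 rose and 2 fell by either adjustment (median 0.27, camera adjusted p = 0.00857, and 0.238 with an estimated correlation). Eln and Ltbp2 rose, the latter with a log2 fold change of 1.70, while Ltbp4, whose protein assists elastic fibre assembly, fell with -1.08. In the TGF-beta list 10 of 21 genes rose and 1 fell by either adjustment (median 0.49, camera adjusted p = 1.35e-05, and 0.245 with an estimated correlation). Its mean z-score was -1.475 in Saline 8, -0.684 in Saline 2 and -0.628 in Saline 7, against -0.212 to 0.128 in the other saline and 0.050 to 0.657 in the Ang II libraries. Without those 3 libraries the median was 0.35, and the list was still called higher with the preset correlation. Tgfbr3, the type III receptor, fell from 27.3 ± 7.33 to 8.22 ± 2.24 FPKM.

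Cell cycle genes rose almost throughout: 24 of 28 were higher and none lower, or 25 adjusted over the list alone (median 1.32, camera adjusted p = 1.05e-26, and 0.0369 with an estimated correlation). Ccnb1 (cyclin B1) rose from 0.427 ± 0.216 to 7.25 ± 2.34 FPKM and Cdc20, an activator of the anaphase complex, from 2.46 ± 0.389 to 13.7 ± 3.80 FPKM. In the unfolded protein response list 13 of 20 genes rose and 1 fell, or 13 and 2 adjusted over the list alone (median 0.49, camera adjusted p = 1.46e-05, and 0.419 with an estimated correlation). Its mean z-score was highest in Ang II 3 (1.268), Ang II 1 (1.095) and Ang II 8 (0.765) and lowest in Saline 8 (-1.097). Saline 7 (0.282) lay above Ang II 2, Ang II 5, Ang II 6 and Ang II 7 (-0.091, -0.161, 0.048 and -0.083). Pdia4 and Pdia6, which form disulphide bonds in the endoplasmic reticulum, rose by 0.98 and 0.71 on the log2 scale. Ddit3 had a log2 fold change of -0.95, and 10.9% of its exon bases overlap other gene models, so its value is uncertain.

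Of 21 contractile genes of smooth muscle tested, 9 fell and 1 rose by either adjustment (median -0.33; -0.21 relative to the median of all genes), and 8 fell and 1 rose after median ratio scaling. The list was not called by camera (adjusted p = 0.0774, and adjusted p = 0.647 with an estimated correlation). It was called lower in 6 of 33 alternatives. Among these were leaving out Saline 2 (adjusted p = 0.0302) or Ang II 8 (adjusted p = 0.0436) and the adipocyte score as a covariate (adjusted p = 0.0117). Tpm2 (tropomyosin 2) fell from 2090 ± 491 to 1073 ± 164 FPKM and Myh11 with a log2 fold change of -0.88, while Ldb3 had a log2 fold change of 0.29 (limma adjusted p = 0.0383), a call that held in 16 of 33 alternatives. Acta2 (smooth muscle actin) held 6887 ± 1279 FPKM with saline and 5512 ± 869 FPKM with Ang II, a log2 fold change of -0.32 that did not pass the test (limma adjusted p = 0.113). It passed in 3 of 33 alternatives, which were quantile normalization (-0.56, adjusted p = 0.0259), sample weights in limma (adjusted p = 0.0240) and the Wilcoxon test (exact where there are no ties, adjusted p = 0.0338). Tagln (transgelin) was listed at 69.6 ± 26.8 and 62.0 ± 23.2 FPKM (limma adjusted p = 0.604). As 67.9% of the exon bases of Tagln overlap Pcsk7 or Gm48529, its level is uncertain. Of 18 genes of vascular tone and nitric oxide signalling, 7 fell and 1 rose by either adjustment (median -0.47, camera adjusted p = 0.173). After median ratio scaling 3 fell and 1 rose. The list was called lower in 7 of 33 alternatives, with adjusted p from 0.00147 (without Saline 2, Saline 7 and Saline 8) to 0.795 (estimated correlation) over all of them. Gucy1a1, a subunit of the nitric oxide receptor, fell with a log2 fold change of -1.04 and the phosphodiesterase gene Pde5a with -0.98. In the list of modulated smooth muscle 10 of 18 genes rose and 2 fell by either adjustment (median 0.73, camera adjusted p = 2.35e-05, and adjusted p = 0.399 with an estimated correlation). Its mean z-score was lowest in Saline 8 (-1.602). Ang II 2 (-0.216) and Ang II 8 (-0.132) lay below Saline 1 (0.303) and Saline 2 (0.044), while the other Ang II libraries lay above every saline library. Cd44 rose from 12.4 ± 3.43 to 36.4 ± 11.3 FPKM and the stem cell antigen gene Ly6a fell from 110 ± 39.1 to 60.6 ± 19.0 FPKM.

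**Figure D3:**
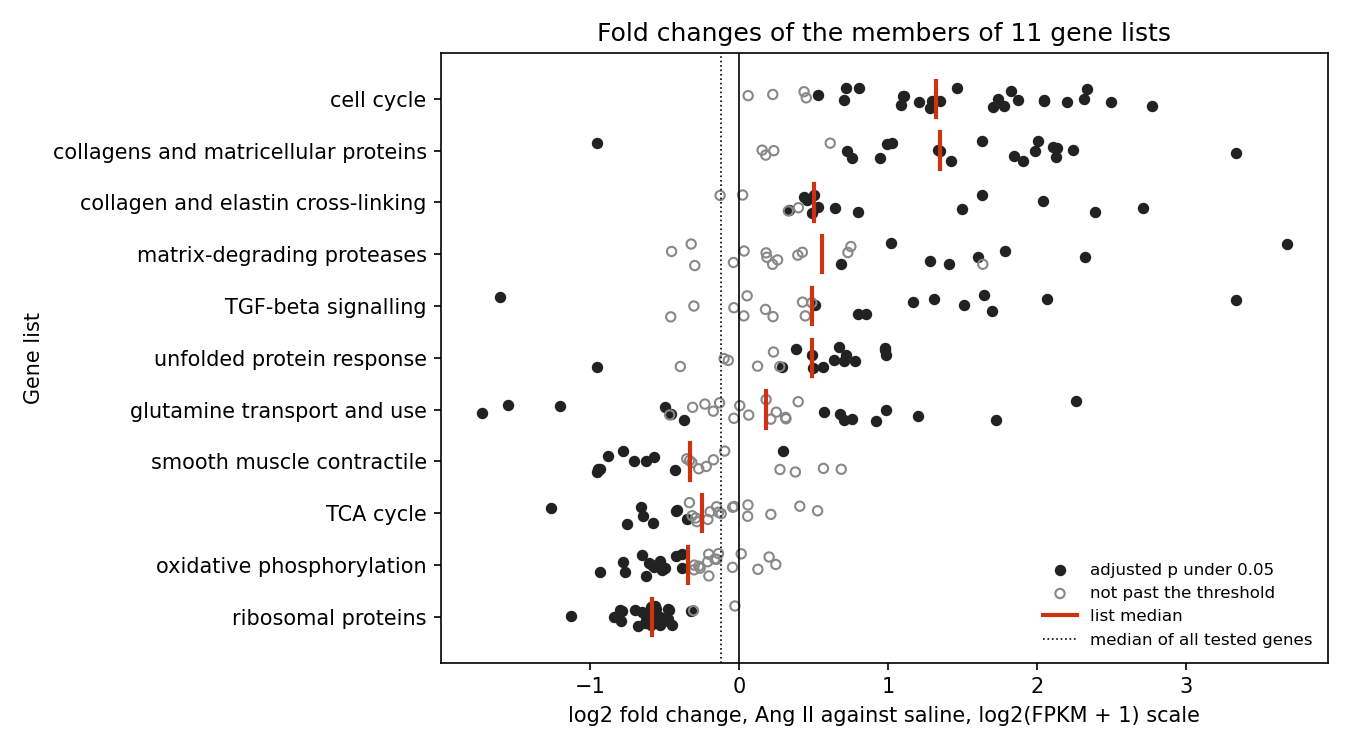
Each point is 1 gene of a list named on the vertical axis, with its log2 fold change between Ang II and saline on the horizontal axis (log2(FPKM + 1) scale); filled points passed an adjusted p of 0.05, red lines are list medians and the dotted line is the median of all tested genes at -0.12. Cell cycle genes have a median of 1.32 and ribosomal protein genes a median of -0.59.

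Of 24 genes of the TCA cycle 8 fell and none rose, or 10 fell and 1 rose adjusted over the list alone (median -0.25, camera adjusted p = 0.0766; called lower in 8 of 33 alternatives, among them without Saline 2, Saline 8 or Ang II 8 at 0.0302, 0.0216 and 0.0425; adjusted p = 0.704 with an estimated correlation), and 6 fell and 2 rose after median ratio scaling. Idh2, the mitochondrial isocitrate dehydrogenase that forms 2-oxoglutarate, fell from 155 ± 22.1 to 63.8 ± 5.53 FPKM (log2 fold change -1.26, SE 0.10, limma adjusted p = 9.16e-08). Of 30 genes of oxidative phosphorylation 15 fell and none rose, or 16 fell adjusted over the list alone (median -0.34, camera adjusted p = 0.0028, and adjusted p = 0.565 with an estimated correlation). After median ratio scaling 9 fell, and after quantile normalization 11 fell, 1 rose and the list was not called (adjusted p = 0.0546). Ndufv1, of complex I, fell from 145 ± 53.9 to 72.5 ± 8.08 FPKM. Genes of glycolysis went both ways, with 4 higher and 5 lower of 19 by either adjustment (camera adjusted p = 0.998) and 4 higher and 2 lower after median ratio scaling; Eno1 rose by 0.44 on the log2 scale. In the redox and ferroptosis list 7 of 22 genes rose and 4 fell, or 7 and 5 adjusted over the list alone (median 0.22, camera adjusted p = 0.0916). That list was called higher without Saline 1 (median 0.28, adjusted p = 0.0391) and with the replicate number as a block (adjusted p = 0.0266, and 0.0127 with GC and length trends removed too), and had an adjusted p = 0.704 with an estimated correlation. Hmox1 (haem oxygenase 1) rose from 6.09 ± 3.96 to 36.7 ± 29.8 FPKM and Fth1 (ferritin heavy chain) fell from 2883 ± 704 to 1375 ± 248 FPKM.

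Chromatin regulators were not called as groups. Of 21 demethylases that use 2-oxoglutarate, 7 fell and none rose by either adjustment, but 2 fell and 2 rose after median ratio scaling. The median changed sign from -0.05 to 0.09. With the FPKM as deposited camera had the direction up (adjusted p = 0.998), and the median was 0.067 relative to the median of all genes. Kdm4b, a histone demethylase, fell with a log2 fold change of -0.60 and Tet1, which oxidises methylated cytosine, with -0.72. Of 27 writers of chromatin and DNA methylation marks, 9 fell and 1 rose by either adjustment (camera adjusted p = 0.475), and 2 fell and 2 rose after median ratio scaling, where the median changed sign from -0.11 to 0.02. Ezh2, a methyltransferase of histone H3, rose from 3.92 ± 0.603 to 7.08 ± 1.23 FPKM, and Hdac5, a histone deacetylase, fell from 201 ± 68.6 to 88.9 ± 10.97 FPKM.

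Ribosomal protein genes formed the other list called lower: 30 of 32 fell and none rose, or 31 adjusted over the list alone (median -0.59; -0.47 relative to the median of all genes, camera adjusted p = 4.19e-08, and adjusted p = 0.565 with an estimated correlation). After median ratio scaling 15 fell. The mean z-score of the list was highest in Saline 7 (1.655) and Saline 8 (1.349), whose deviations also rose most with GC content (Spearman 0.412 and 0.370), and was -0.070 in Saline 4 and -0.283 in Saline 5. It was -1.146 to 0.121 in the Ang II libraries. The median shrank to -0.325 with quantile normalization, -0.43 with GC and length trends removed and -0.42 without Saline 2, Saline 7 and Saline 8. Rpl3 fell from 625 ± 87.4 to 422 ± 41.9 FPKM. Ribosomal protein genes have many processed pseudogenes, so reads can be shared. No mitochondrially encoded gene changed by either adjustment, yet the list was called higher by camera (median 0.29, adjusted p = 0.0274, and adjusted p = 0.777 with an estimated correlation). That call was lost after median ratio scaling (median 0.44, adjusted p = 0.0659) and quantile normalization (median 0.22, adjusted p = 0.379). It was also lost without Saline 3, Saline 5, Ang II 1 or Ang II 2 (medians 0.185, 0.222, 0.115 and 0.206, adjusted p = 0.106, 0.06, 0.117 and 0.0991). mt-Co1 held 16518 ± 6593 FPKM with saline and 23919 ± 9878 FPKM with Ang II (limma adjusted p = 0.141).

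Chemokine and cytokine genes were called higher, with 6 of 20 higher and 1 lower by either adjustment (median 0.60, camera adjusted p = 0.000671, and adjusted p = 0.564 with an estimated correlation). The list was not called without Ang II 1 and Ang II 3 or with the macrophage score as a covariate (medians 0.38 and 0.13). Those libraries had the highest mean z-scores of this list (1.716 and 0.994), as well as of the neutrophil and macrophage markers. Leaving them out therefore lowers the list in any case. Ccl2 rose by 1.93 and Cxcl12 by 1.39 on the log2 scale, and Csf1 fell with a log2 fold change of -0.72. Macrophage and monocyte markers were higher too, with 6 of 22 higher and none lower, or 5 adjusted over the list alone (median 1.00, camera adjusted p = 5.69e-07, and adjusted p = 0.551 with an estimated correlation). Their mean z-score ran from -0.32 (Ang II 5) to 2.13 (Ang II 1) with Ang II and from -1.10 (Saline 7) to 0.60 (Saline 1) with saline. Ang II 4, Ang II 5, Ang II 7 and Ang II 8 lay below both Saline 1 and Saline 2 (0.183). F13a1 rose from 2.27 ± 1.08 to 9.16 ± 4.71 FPKM and Adgre1 from 1.68 ± 1.92 to 5.77 ± 3.70 FPKM. Of 4 neutrophil markers 1 rose, S100a9, from 0.779 ± 1.42 to 11.9 ± 17.1 FPKM, and 4 rose adjusted over the list alone; the list was too small to test. In 5 of 33 alternatives it had enough tested members and was called higher by camera (adjusted p from 0.00406 without a filter to 0.0396 with the reads of the 100 largest genes taken out). Among these were leaving out Saline 8 (0.0192) or Ang II 2 (0.0147).

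White adipocyte markers fell in 4 of 14 cases and brown adipocyte markers in 3 of 9, none rose, and the counts were the same adjusted over the list alone (medians -1.02 and -0.61, camera adjusted p = 0.135 and 0.443). After median ratio scaling 3 white adipocyte markers fell and that list was called lower (adjusted p = 0.0477), as it was in 5 of 33 alternatives, among them the replicate number as a block (adjusted p = 0.0146). With an estimated correlation the list had an adjusted p = 0.795. Its mean z-score was 1.27 in Saline 8, 1.19 in Saline 6 and 1.04 in Saline 2. Plin4 fell from 113 ± 36.1 to 53.3 ± 10.2 FPKM and Cidea from 22.8 ± 13.5 to 7.44 ± 3.05 FPKM. Of 17 endothelial markers 1 rose and 3 fell, or 1 and 2 adjusted over the list alone (median -0.09 and, after median ratio scaling, 0.03; camera adjusted p = 0.757, direction up). Erg rose by 0.72 on the log2 scale, a call that held in 22 of 33 alternatives, and Cldn5 fell with -1.10. Of 16 fibroblast markers 2 rose, Smoc2 and Cd248, and 2 fell by either adjustment (median -0.08 and, after median ratio scaling, 0.05; camera adjusted p = 0.436, direction up).

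Of 17 circadian clock genes 2 rose and 8 fell by either adjustment (median -0.53, camera adjusted p = 0.126). Without Saline 1 the list was called lower (adjusted p = 0.0423), and its adjusted p with an estimated correlation was 0.565. Tef, a clock-controlled transcription factor, fell from 470 ± 132 to 235 ± 44.8 FPKM, and Rora, a nuclear receptor of the clock, rose by 0.64 on the log2 scale. Without Saline 2, Saline 7 and Saline 8 the log2 fold change of Rora was 0.29 and did not pass (limma adjusted p = 0.0824), and its call held in 30 of 33 alternatives. Of 22 immediate early and heat shock genes 2 rose and 3 fell over all genes tested, none changed adjusted over the list alone, and after median ratio scaling 2 rose and none fell (median -0.31, camera direction up, adjusted p = 0.757, and 0.968 with an estimated correlation). That list was called higher with sample weights (median 0.15, adjusted p = 0.0440) and without Saline 2, Saline 7 and Saline 8 (median 0.23, adjusted p = 0.0224). Myc rose by 1.26 on the log2 scale, a call that held in 29 of 33 alternatives. Nr4a1 had a log2 fold change of -1.67 (SE 0.57, limma adjusted p = 0.0317), a call that held in 11 of 33 alternatives. Of 13 genes of cartilage and bone 4 rose and 3 fell, or 5 and 3 adjusted over the list alone (median 0.38, camera adjusted p = 0.120, and 0.565 with an estimated correlation). The list was called higher without a filter (adjusted p = 0.0424) and with GC and length trends removed (adjusted p = 0.0457). Acan (aggrecan) rose from 6.52 ± 2.36 to 46.2 ± 15.4 FPKM and Chad (chondroadherin) by 2.27 on the log2 scale, while Alpl, the alkaline phosphatase of mineralising tissue, fell from 16.9 ± 4.83 to 5.11 ± 2.503 FPKM. Of 25 interferon response genes 7 fell and none rose by either adjustment (median -0.20, camera adjusted p = 0.445), and 6 fell and 1 rose after median ratio scaling. That list was called lower in 3 of 33 alternatives. These were without Ang II 1 (median -0.38, adjusted p = 0.0217), without Ang II 1 and Ang II 3 (-0.34, 0.0292) and with the macrophage score as a covariate (-0.40, 0.0304). Its adjusted p with an estimated correlation was 0.859.

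Markers of other cell types were not called as lists. None of 9 dendritic cell markers, 7 T and NK lymphocyte markers, 7 B and plasma cell markers, 7 skeletal muscle markers or 5 red blood cell markers changed by either adjustment (camera adjusted p = 0.445, 0.474, 0.465, 0.858 and 0.474). Their medians were 0.03, -0.02, -0.60, -0.26 and 0.14. Camera, which compares a list with all other genes, had the direction up for the T and NK lymphocyte and skeletal muscle lists. Relative to the median of all genes their medians were 0.102 and -0.141, so only that of skeletal muscle was opposite to the direction. Of 6 cardiac muscle markers 1 rose and 1 fell by either adjustment (median -0.09, mean 0.05, camera direction up, adjusted p = 0.474). These were Ankrd1, a stress-responsive gene, with a log2 fold change of 1.82 and Tnni3, a troponin, with -1.17. Of 7 nerve and Schwann cell markers 1 rose and 2 fell, or 2 and 2 adjusted over the list alone (median 0.05, camera adjusted p = 0.592). The mast cell list (2 tested, median -0.39) and the mesothelial list (1 tested, log2 fold change -0.64, lower adjusted over the list alone) were too small to test, and none of their members changed over all genes tested.

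Angiotensin receptor and endothelin genes were not called as a list, with 1 of 16 higher and 4 lower by either adjustment (camera adjusted p = 0.757). Rcan1, an inhibitor of calcineurin, rose from 26.9 ± 6.04 to 91.9 ± 24.3 FPKM, and Ednra, the endothelin A receptor, fell from 1.61 ± 0.531 to 0.599 ± 0.142 FPKM. Agtr1a, the main Ang II receptor of the vessel wall, held 0.474 ± 0.332 and 0.620 ± 0.123 FPKM (limma adjusted p = 0.358). Apoe was listed at 37.0 ± 32.2 FPKM with saline and 12.1 ± 3.24 FPKM with Ang II (limma adjusted p = 0.0104). The treatment protocol in the labels gives the mice as Apoe-/-, but the library names there carry the letters WT in all 16 samples. Neither the labels nor these values settle the genotype.

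The spread within groups was measured as the mean distance (1 minus Pearson r) between libraries of a group. It was 0.0278 among Ang II and 0.0524 among saline libraries. The mean distance of a library to its own group was 0.0223 to 0.0371 with Ang II and 0.0412 to 0.0961 with saline, where Saline 8 had the highest value and adds to that of every other saline library. The exact permutation test of the labels planned for this gave a two-sided p = 0.332, but its permuted groups also hold the differences between Ang II and saline, so it does not test for equal spread. With each gene centred on its group mean, a test added after seeing the data, the values were 0.0276 and 0.0551 (approximate permutation p = 0.0152). Centring ties the values within a real group to each other but not those within a permuted group, so p-values of centred tests are approximate. Without Saline 8 that centred difference did not pass (0.0277 and 0.0393, approximate permutation p = 0.224). Without Saline 2, Saline 7 and Saline 8 the centred saline value was 0.0212, below that of Ang II (approximate permutation p = 0.341).

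Over both groups 4 relations were tested, each within a group of 8 libraries, and none passed after Benjamini-Hochberg adjustment. Among saline libraries Slc1a5 ran against the contractile score with Pearson r = -0.729 (exact permutation p = 0.0344, adjusted p = 0.0688) and Spearman rho = -0.571 (exact p = 0.151, adjusted p = 0.302). Without Saline 2 and Saline 8, the libraries farthest from the median, r was -0.245 (exact p = 0.615), so that relation rests on those libraries. Among Ang II libraries Slc1a5 had r = 0.050 with the contractile score (exact p = 0.904, adjusted p = 0.904) and rho = -0.119 (exact p = 0.793, adjusted p = 0.793). The macrophage score against the contractile score gave r = -0.758 among Ang II libraries (exact p = 0.0297, adjusted p = 0.0688) and rho = -0.762 (exact p = 0.0368, adjusted p = 0.147). Without Ang II 1 and Ang II 5 it gave r = -0.777 (exact p = 0.0556). Among saline libraries it gave r = -0.311 (exact p = 0.452, adjusted p = 0.603) and rho = -0.262 (exact p = 0.536, adjusted p = 0.715).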

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

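Chosen only after the result was seen were the test that took the reads of the 100 genes with the most reads out of the library totals, the removal of GC and length trends, the macrophage and monocyte covariate, the list of ATF4 targets, and leaving out Saline 7 and Saline 8.

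Whether the number of gene lists called by camera exceeds chance could not be decided. Of 100 splits of the 16 libraries into 8 and 8, 36 called at least the 14 lists of the real split. The highest other split called 22. Many of the other splits had 5 or 6 Ang II libraries on the same side, so they keep part of the treatment difference and do not measure chance alone. Even splits, with 4 Ang II libraries on each side, also called up to 19 lists, so the 14 lists are not set apart from chance either. For the counts of genes no other split reached the real values, which makes chance unlikely. With only 100 splits run, chance is not excluded. Of the 99 other splits 97 gave 0 genes. These splits put Ang II and saline libraries together, so the difference between treatments adds to their spread and lowers their counts. The real split gave 1431 genes higher and 3741 lower, where the highest other split gave 779, and 380 and 486 genes at least 2-fold higher and lower, where the highest other split gave 112. In each of these 4 counts 1 of the 100 splits, the real one, gave as many.

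More genes were lower than higher with Ang II, with 72.3% of the changed genes lower. With GC content and transcript length trends removed 73.7% were lower. That removal keeps the mean level of each library over the genes with a GC value. It could therefore hardly move this balance, and it does not decide whether these trends had a part. Without Saline 7 and Saline 8 75.8% were lower, which argues against those libraries as the cause. With the reads of the 100 largest genes taken out of each library total 49.7% were lower. That step rescales all genes of a library alike, and a fall in most other genes would raise the share of these 100 as well, so it does not tell these apart, and the excess of lower genes stays unexplained. Whether Ang II lowers the RNA of most genes per cell stays open, since FPKM holds no measure of total RNA.

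Slc1a5 was lower with Ang II. With the adipocyte score as a covariate its log2 fold change was -0.90 (limma adjusted p = 0.000341), against -1.21 without it. Fat left on the saline aortas may account for a part. A score of markers measures fat incompletely, so fat as the whole cause is not excluded. Among saline libraries, Saline 8, Saline 2 and Saline 6 held the most Slc1a5 (282, 199 and 165 FPKM) and the highest white adipocyte scores (1.27, 1.04 and 1.19). Ang II 8, with a score of 0.604, held 71.4 FPKM, against 0.407 and 148 FPKM in Saline 3. With GC and length trends removed it was -1.05, which argues against these trends as the whole cause. A lower output of the amino acid response of the transcription factor ATF4 could not be decided. Its targets without Slc1a5 had a median of -0.11, against -0.12 over all tested genes, and 9 rose and 4 fell of 28. Camera gave that list the direction up, opposite to a lower output, but the list did not pass (camera p = 0.064, and 0.273 with an estimated correlation). A lower level of Slc1a5 RNA in cells of the wall stays open as a hypothesis. The test of Slc1a5 was fixed before the data were examined, but the gene was taken from the title of the study, so its choice may rest on these same data.

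Cell cycle genes were higher with Ang II. With the macrophage and monocyte score as a covariate their median log2 fold change was 1.25, against 1.32 without it. This argues against the amount of these cells, as the score measures it, as the whole cause. A score of markers measures these cells incompletely and does not measure their division, so they are not excluded. With GC and length trends removed it was 1.31, which argues against the trends. Division of cells of the wall with Ang II stays open as a hypothesis, and bulk RNA does not say which cells divided. For the ribosomal protein list the median was -0.43 with GC and length trends removed, against -0.59 before.

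In 21 of 252 sets of 8 values (8.33%) 1 library lay far from the other 7 by Dixon's test. For normally distributed values chance gives this in about 5% of sets, or 1 in 20. The sets share libraries and genes, so 8.33% was not tested against 5%. Among genes in Ang II libraries, Esm1 was 131 FPKM in Ang II 6 (others 6.54 to 20.7) and Cd248 71.0 in the same library (20.2 to 32.2). Fth1 was 870 in Ang II 5 (1274 to 1669). Slc1a5 was 106 in Ang II 2 (58.8 to 74.3), Hdac5 114 (78.4 to 93.1) and Erg 38.2 (56.9 to 78.9) in the same library. Ang II 1 held 32.0 FPKM of Mmp9 (0.138 to 2.78), 11.9 of Kdm4b (16.3 to 19.9) and 11.04 of Alpl (3.28 to 5.52).

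Among genes in saline libraries, Adm was 9.80 FPKM in Saline 4 (others 15.8 to 23.9) and S100a9 4.17 in Saline 4 (0 to 1.11). Cd44 was 5.00 in Saline 8 (10.3 to 16.2), Plin4 198 in Saline 8 (83.9 to 116) and Cldn5 29.0 in Saline 6 (40.6 to 53.5). Among mean z-scores of lists, the TCA cycle list was 0.227 in Ang II 8 (-0.676 to -0.275), the fibroblast list 0.782 in Ang II 1 (-0.411 to 0.143) and the cardiac muscle list 0.806 in Ang II 5 (-0.342 to 0.143). The skeletal muscle list was 1.81 in Ang II 5 (-0.725 to -0.176) and 2.32 in Saline 2 (-0.369 to 0.017), and the B and plasma cell list was 3.12 in Saline 6 (-0.470 to 0.622). Genes of ribosomal RNA and Gm23935 took 2.83% of the reads of Saline 2 (0.230% to 0.380% in the other saline libraries).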

How the results depend on the processing

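Chosen only after the result was seen were voom, the GC and length correction, the macrophage covariate, the sets of 2 or 3 libraries left out, the reads of the 100 largest genes taken out, and the spread with genes centred on their group mean. Slc1a5 stayed past the threshold in all 33 alternatives (-1.29 to -0.90), and 61 of the 78 named genes past it did so in every alternative run for them. Of the other 17, the call held in 32 of 33 for Ly6a, Ltbp4, Eno1, Tet1, Ddit3, Cldn5 and Cidea, 31 for Adgre1, S100a9, Tnni3 and Apoe, 30 for Rora, 29 for Myc, 25 for Spp1, 22 for Erg, 16 for Ldb3 and 11 for Nr4a1. No gene called was called in the other direction under any alternative. For results that moved or reversed the cause was not tested. The difference in spread with genes centred was -0.0275, now past the threshold by an approximate p (permutation p = 0.0152). Without Saline 2, 7 and 8 as well it was 0.00653.

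With an estimated correlation 4 lists were called. With a pseudocount of 0.1, 659 genes were at least 2-fold higher and 888 lower, and the T and NK lymphocyte median was 0.295. Without a filter the cardiac muscle median was 0.028.

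With quantile normalization 2270 genes were higher and 2374 lower. Tagln was 0.038, and medians were 0.061 for demethylases, 0.098 for endothelial and 0.034 for fibroblast markers. Among Ang II libraries r was -0.102 for Slc1a5 and -0.86 for macrophages against the contractile list, the latter now past the threshold (Benjamini-Hochberg adjusted exact permutation p = 0.0188). With median ratio scaling 2241 were higher, 2115 lower and 313 at least 2-fold lower. Medians were 0.085 for demethylases, 0.02 for writers, 0.05 for T and NK lymphocyte, 0.029 for endothelial, 0.053 for fibroblast and 0.004 for cardiac muscle markers. With voom 2227 were higher, 2051 lower and 830 at least 2-fold higher, and the same 6 medians were 0.091, 0.023, 0.575, 0.045, 0.027 and 0.012. With the reads of the 100 largest genes taken out 2211 were higher, 2185 lower and 597 at least 2-fold higher, and these medians were 0.098, 0.033, 0.067, 0.042, 0.063 and 0.002.

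With sample weights Tagln was 0.056, and medians were 0.15 for immediate early genes (now called higher, camera adjusted p = 0.0440), -0.165 for dendritic, 0.099 for skeletal muscle, 0.05 for cardiac muscle and -0.004 for red blood cell markers. With the adipocyte covariate 745 were higher, 1697 lower and 313 at least 2-fold lower, and medians were -0.1 for dendritic and 0.404 for white adipocyte markers. With the macrophage covariate 777 were higher and 1997 lower, and Mmp9 was -0.255. Medians there were 0.025 for demethylases, -0.199 for macrophage, -0.54 for dendritic, 0.155 for endothelial, 0.114 for cardiac muscle, -0.059 for nerve, -0.439 for red blood cell and -0.145 for mitochondrially encoded genes. With GC and length trends removed, with or without the block, T and NK lymphocyte, endothelial and cardiac muscle medians were each 0.026.

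The labels give a saline and an Ang II sample the same number without stating a pairing. With that number as a block 1414 genes were higher and 3531 lower, and 4632 of the 5172 calls were kept. The redox and ferroptosis list and the white adipocyte list, not called in the planned test, were called with the block (camera adjusted p = 0.0266 and 0.0146). Nr4a1 and Ldb3 were not called with it (limma adjusted p = 0.0668 and 0.0614). Correlations within pairs ran from -0.246 to 0.385.

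Without Saline 7 and 8 Tagln was 0.067, and medians were 0.069 for immediate early genes, -0.221 for dendritic and 0.039 for cardiac muscle markers. Without Saline 2, 7 and 8 Tagln was 0.163, these medians were 0.232 (now called higher, camera adjusted p = 0.0224), -0.25 and 0.071, the skeletal muscle median was 0.223 and the difference in spread was 0.00728. Without Ang II 1 and 3 medians were 0.002 for demethylases, -0.232 for dendritic, 0.063 for cardiac muscle, -0.043 for nerve and -0.475 for red blood cell markers.

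With 1 library left out, 1170 to 1533 genes were higher and 3239 to 3896 lower, 327 to 432 at least 2-fold higher and 367 to 604 lower. Slc1a5 ran from -1.29 to -1.093, lists called from 13 to 16 and the difference in spread from -0.0284 to -0.0101. Medians ran from -0.115 to 0.027 for demethylases, -0.113 to 0.168 for dendritic, -0.124 to 0.117 for T and NK lymphocyte, -0.19 to 0.183 for endothelial, -0.233 to 0.023 for fibroblast, -0.023 to 0.101 for nerve and -0.324 to 0.565 for red blood cell markers.

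Of 1320 list medians under alternatives 90 had the other sign, 4 of them in lists called in either fit. On simulated data limma recovered 26.9% of genes changed 1.5-fold. Far fewer genes were changed there than passed in these data, so the share found here may differ.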

Other observations

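All tests here were chosen only after the result was seen. Of 13 families of transcription factors in the deposited annotation none was called by camera. The ETS family had 6 genes higher and 1 lower of 18 (median 0.17, camera adjusted p = 0.0636) and the homeobox family 4 higher and 23 lower of 67 (median -0.31, camera adjusted p = 0.183). Mitochondrial mRNA held 5.30% to 11.1% of the recovered reads in saline and 6.04% to 19.0% in Ang II libraries, with the highest share in Ang II 1.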
